A study of Homo sapiens with 12 samples.

How the data were processed

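RCC4 cells were profiled on 12 single-channel Affymetrix arrays, 3 in each of 4 groups formed by siRNA (non-targeting or against YAP) and treatment (DMSO or erastin). Groups and replicate numbers came from the sample titles. The values were made by the authors with Affymetrix Expression Console and RMA, per the submitters' processing notes, whose versions and settings are not given in the sources used here. RMA subtracts background, equalises the distribution of probe signals between arrays and summarises the probes of each probe set. The deposited values are on the log2 scale, as their range of 2.02 to 14.4 and their near-equal array medians show, and were not centred per probe set. Because RMA equalises the arrays, a change of total RNA per cell would not be seen, and fold changes of dim genes are compressed toward 0. The array type and scan dates are not given in the sources used here, so no batch could be tested.

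The table held 22277 probe sets, of which 62 were array controls. A platform annotation table gave exactly 1 gene symbol for 19065 probe sets, several for 1043 and none for 2107. Symbols were brought up to date through gene identifiers in a RefSeq gene table, which matched 19053 probe sets and changed 0 symbols. Probe sets with several symbols or none were not named or used at the gene level. For each of 11963 genes the probe set with the highest mean over all 12 arrays was taken; 4310 genes had more than 1. Among 93 calls of named genes with further probe sets, 0 had another probe set called in the opposite direction and 24 had no other probe set called. Among the 24 were FBN1 after silencing, IL11 and HMGCS1 after silencing in DMSO and ALOX5 after silencing under erastin. Others were GDF15, KLF4, EGR1, DUSP7, PLAUR and AKR1C1 with erastin in control cells, and CTH and KLF4 with erastin after silencing.

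Differences were tested with limma 3.58.1 in R 4.3.3. A linear model with a mean per group was fitted to all 12 arrays, which leaves 8 residual degrees of freedom, and variances were moderated by empirical Bayes (4.17 prior degrees of freedom). The 5 comparisons were siYAP against siNT in DMSO and under erastin, erastin against DMSO in siNT and in siYAP cells, and the interaction, which is the difference between both erastin responses. Benjamini-Hochberg adjustment ran over all genes within a comparison, and genes at adjusted p under 0.05 were called. Replicates are biological triplicates per the labels, but nothing says how separately they were cultured, so p-values measure the spread between these samples. All adjusted p-values for genes are limma's.

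A total of 21 gene lists were tested with camera on the moderated statistics, with a preset correlation between genes of 0.01, two-sided, and Benjamini-Hochberg adjustment over all 105 tests of lists and comparisons. As alternatives the correlation was estimated for each list, and fry was run, which tests whether the genes of a list move on balance in a direction or, in its mixed form, in either. Camera with the preset correlation called 34 of the 105 (17 upward, 17 downward), and 5 with an estimated correlation. These 5 were the ATF4 list in the first 4 comparisons and p53 targets with erastin in control cells. Some genes stand on more than 1 list, such as SLC7A11, SLC3A2, ATF3, STC2, ANGPTL4 and HMOX1.

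Genes named in the text were chosen by a fixed rule. It took 11 genes in every comparison (YAP1, WWTR1, SKP2, EMP1, ANGPTL4, ACSL4, TFRC, SLC7A11, CHAC1, GPX4 and NOX4), the 8 largest rises and 8 largest falls among called genes whose arrays did not overlap between groups, and up to 4 called members of each list with the largest change. Predicted loci were passed over.

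The test was checked on simulated data with the real genes' means and spread, in which 200 of 11963 genes were changed by known amounts. For YAP silencing in DMSO it called 16% of genes changed by 0.25 on the log2 scale and 100% of those changed by 0.5, 1 or 2, and 3.07% of its calls were false. For erastin in control cells it called 18% of genes changed by 0.25 and 94% of those changed by 0.5, and 3.11% of its calls were false. These shares depend on the number of changed genes and on the independent noise of the simulation, so they are not the power for the real data. Silencing in DMSO called 4030 real genes, some with a log2 change as small as 0.132.

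The comparisons, gene lists, rule for named genes and the following alternatives were fixed before the data were examined. The alternatives were a fit of only the 6 arrays compared, the replicate number as a block, each array centred on its median, quantile normalization of the deposited values, removal of the dimmest 30% of probe sets, the mean of a gene's probe sets, every probe set on its own, a trended and robust variance model, array weights, a 2-fold minimum, the zero transformation of the submitters' design text (each array minus the control mean, called when all 3 arrays lay beyond 1 log2 unit), and leaving out each array. Added after seeing the data were the ACTB 3' to 5' difference as a covariate, the removal of 2 arrays together (siNT with erastin replicate 3, which deviated most from its group, and siYAP with erastin replicate 2, with the highest remaining YAP1), and an estimated list correlation in the blocked fit. Overlap of calls was set against the product of both list lengths divided by the number of genes. Arrays of a group shared at most 18 identical values among all probe sets, so none was a copy. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Genes without a probe set that has exactly 1 symbol in these tables were not analysed here.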

Results

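Gene expression was measured on 12 Affymetrix arrays of RCC4 cells, an established human clear cell renal carcinoma line that lacks functional VHL and therefore has high hypoxia-inducible factor activity. Cells received an siRNA against YAP (YAP1, the transcriptional co-activator at the end of the Hippo pathway) or a non-targeting siRNA (siNT). After 2 days they were given erastin at 1 µM or its solvent DMSO for 7 hours. Erastin blocks the cystine importer system xc-, whose transport subunit is SLC7A11, and can set off ferroptosis, an iron-dependent form of cell death. The 4 groups (siNT with DMSO, siNT with erastin, siYAP with DMSO and siYAP with erastin) held 3 arrays each, described by the submitters as biological replicates. The design addresses how YAP silencing changed expression, and the erastin arrays let the same question be asked in treated cells.

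Each array gave values for 22277 probe sets on the log2 scale, from 2.02 to 14.4 over all arrays, and array medians lay between 6.49 and 6.52. Arrays of the same group correlated at 0.9962 to 0.9987. The first principal component held 71.3% of the variance and separated every siYAP array from every siNT array. The next components held 6.9% and 5.1%. After the choice of a single probe set per gene, 11963 genes were tested. With 3 arrays per group, their number limits the precision: the median standard error of a log2 fold change was 0.078.

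The silenced gene was measured first. YAP1 stood at 8.47 to 8.65 on the 6 siNT arrays. It was 4.18, 4.88 and 4.81 on the siYAP arrays with DMSO, and 4.68, 6.21 and 4.90 on those with erastin. Mean YAP1 was 8.54 ± 0.06 (SD, n = 3) in siNT with DMSO and 4.62 ± 0.39 in siYAP with DMSO, and it was 8.54 ± 0.09 and 5.26 ± 0.83 in the corresponding erastin groups. YAP1 was lower on every siYAP array than on every siNT array, so every array went the way of its label. The fitted change was 15.1-fold lower in DMSO and 9.72-fold lower under erastin. Markers of endothelial cells, fibroblasts and immune cells had median levels of 4.53, 4.62 and 4.9, and YAP1 in siYAP with DMSO lay near them, so the size of its fall is uncertain. The same holds for the changes below of SUV39H2, CPEB3, FBN1, COL5A2, COL6A3, ALOX5 and, after silencing, INHBE, whose lowest group means were 3.24, 4.14, 4.69, 4.12, 4.10, 4.51 and 4.43. WWTR1, which encodes the YAP paralogue TAZ, differed by 0.04 in DMSO (adjusted p = 0.637) and by -0.06 under erastin (adjusted p = 0.456) on the log2 scale.

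**Figure D1:**
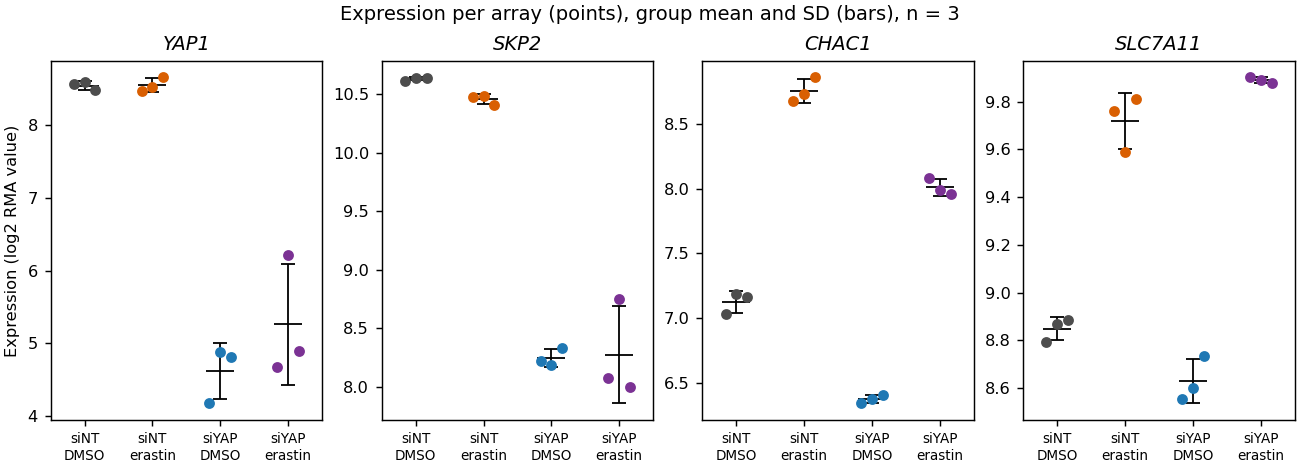
Expression on each array (log2 RMA value, vertical axis, which does not start at 0) of YAP1, SKP2, CHAC1 and SLC7A11 in the 4 groups; points are arrays, horizontal bars group means and error bars SD (n = 3). YAP1 lies between 8.47 and 8.65 on the siNT arrays and between 4.18 and 6.21 on the siYAP arrays, and CHAC1 is higher with erastin in both siRNA groups.

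In DMSO, YAP silencing lowered 36 of 37 genes of S phase and DNA replication and 33 of 34 of G2 and mitosis, and raised 13 of 24 NF-kB and cytokine genes and 22 of 29 interferon response genes. As sets these lists had adjusted p = 0.111, 0.111, 0.151 and 0.403 with an estimated correlation. The largest rises were those of CCL20, a chemokine (7.01-fold), AGT, which encodes angiotensinogen (6.54-fold), and the sodium channel gene SCN3A (5.9-fold). The largest falls after YAP1 itself were those of LYRM1 (7.53-fold lower), the histone methyltransferase gene SUV39H2 (7.13-fold lower), OSTM1 (7.03-fold lower) and PLOD2, a collagen lysyl hydroxylase (6.35-fold lower). SUV39H2 went from 6.08 to 3.24, near the bottom of the scale, so the size and rank of its fall are uncertain. In limma, 4030 of 11963 genes passed an adjusted p of 0.05, of which 2165 were higher and 1865 lower. Among the 324 that changed at least 2-fold, 111 were higher and 213 lower.

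Other large rises were those of IFITM1 (log2 fold change 2.34, SE 0.191), the matricellular gene CCN3 (2.18, SE 0.136), PTX3 (2.12, SE 0.114), IFI27 (2.10, SE 0.243) and CPEB3 (1.91, SE 0.228). SLC11A2, which encodes the iron transporter DMT1, fell by 2.64 (SE 0.164), SPAST by 2.56 (SE 0.127) and the bicarbonate transporter gene SLC4A4 by 2.49 (SE 0.142). Adjusted p for these ranged down to 1.98e-09 (AGT and SCN3A), and for CPEB3 it was 2.73e-05.

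Of 37 measured genes of S phase and DNA replication, 36 fell and none rose, with a median log2 change of -0.92. CDC45, which belongs to the replicative helicase, fell by 1.88, CCNE2 (cyclin E2) by 1.86, PRIM1 by 1.79 and the polymerase gene POLA1 by 1.78. Of 34 genes of G2 and mitosis, 33 fell, with a median of -1.07, among them KIF23 (-1.64), HMMR (-1.59), CDC25C (-1.51) and CCNB2 (-1.40). Both lists moved as sets in camera (adjusted p = 1.82e-41 and 2.68e-45), and neither call held when the correlation between members was estimated (adjusted p = 0.111 for each with an estimated correlation). Adjusted over the list alone, 36 and 33 members were lower as well.

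Of 29 interferon response genes, 22 rose and none fell (24 higher and 1 lower adjusted over the list alone), led by IFI27, IFI6 (1.77), ISG15 (1.28) and OAS1 (1.19). The set shift had adjusted p = 3.31e-06, and adjusted p = 0.403 with an estimated correlation. Of 24 NF-kB and cytokine genes, 13 rose and 1 fell, the same counts as adjusted over the list alone. CXCL8 rose by 1.19 and CCL2 by 1.02, both chemokine genes. IL11 fell by 0.94, and its other probe set was not called. That list gave adjusted p = 5.05e-04, and adjusted p = 0.151 with an estimated correlation. For immediate early genes, 8 of 21 rose and 3 fell (9 and 3 adjusted over the list alone), including SPRY2 (1.25), ATF3 (1.00) and EGR1 (0.69), with adjusted p = 0.00586 and adjusted p = 0.264 with an estimated correlation.

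The ATF4 and amino acid response list, which holds genes induced when amino acids run short, was lower as a set. Of its 36 members 22 fell and 3 rose, also adjusted over the list alone. The neutral amino acid transporter gene SLC1A4 fell by 1.46, the arginine transporter gene SLC7A1 by 1.27 and ASNS, asparagine synthetase, by 1.11. CHAC1, a glutathione-degrading enzyme, fell by 0.75 (adjusted p = 1.62e-06), while ATF3 rose. This shift had adjusted p = 1.79e-10, and adjusted p = 0.0475 with an estimated correlation. It was not called with the replicate block and an estimated correlation together (adjusted p = 0.17).

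NRF2 targets rose in 9 and fell in 3 of 21 cases (9 and 3 adjusted over the list alone, adjusted p = 0.0129, and adjusted p = 0.504 with an estimated correlation). The aldo-keto reductase genes AKR1C3 (1.34), AKR1C1 (1.10), AKR1B10 (0.89) and AKR1C2 (0.89) led the rises. These paralogues are close in sequence, so the value of each is uncertain. Among p53 targets 10 of 20 rose and 3 fell (11 and 3 adjusted over the list alone, adjusted p = 0.0229, and adjusted p = 0.197 with an estimated correlation). TP53I3 rose by 1.40, ZMAT3 by 0.74 and SESN1 by 0.72, and the pro-apoptotic gene PMAIP1 fell by 1.70.

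The fixed list of YAP/TAZ target genes did not move as a set (adjusted p = 0.741). Of 19 measured members 4 rose and 3 fell, also adjusted over the list alone, with a median of -0.01, a mean of 0.06 and a test direction upward. CCN2 (0.76), ANKRD1 (0.83) and GADD45A (0.61) rose, and AMOTL2 fell by 0.51. In the list of Hippo pathway and TEAD factors 2 of 18 rose and 3 fell (the same adjusted over the list alone, adjusted p = 0.906), its median of 0.06 and mean of -0.03 differing in sign. MOB1A, an activator of the LATS kinases, fell by 1.78, and VGLL4, which competes with YAP for TEAD factors, rose by 0.80.

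Genes linked to ferroptosis changed in both directions. Among 26 that promote it, 5 rose and 6 fell (adjusted p = 0.664), and among 16 that protect from it, 4 rose and 4 fell (adjusted p = 0.664). Adjusted over the list alone, the counts were 5 and 6, and 4 and 5. Directional fry gave adjusted p = 0.0147 (downward) for the promoting and 0.0557 for the protective genes. Among the promoting genes the median was above 0 and the mean and test below it, which also held for the hypoxia-inducible factor targets. SKP2, a subunit of an SCF ubiquitin ligase, was 5.21-fold lower, from 10.63 ± 0.01 to 8.25 ± 0.08 (SD, n = 3). EMP1 was 2.56-fold higher (adjusted p = 1.01e-06). ACSL4, which loads polyunsaturated fatty acids into lipids, fell by 0.56 (adjusted p = 8.47e-04), BECN1 by 1.06 and SCD by 0.83. SAT1 rose by 0.81 and CISD1 by 0.57. TFRC, the transferrin receptor, rose by 0.20 (adjusted p = 0.00946) and SLC7A11 fell by 0.22 (adjusted p = 0.0231). GPX4 (0.18, adjusted p = 0.0889), ANGPTL4 (0.04, adjusted p = 0.659) and NOX4 (0.16, adjusted p = 0.39) did not pass the test, and NOX4 lay near the bottom of the scale at 3.47 in siNT with DMSO.

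Other fixed lists did not pass as sets in camera in DMSO. Among them, directional fry called cholesterol synthesis (adjusted p = 1.09e-05) and hypoxia-inducible factor targets (adjusted p = 0.0337) downward. It called heat shock genes (adjusted p = 2.31e-05) and kidney tubule markers (adjusted p = 0.00176) upward. Hypoxia-inducible factor targets were split, with 9 of 27 higher (CA12, 1.04) and 10 lower (ADM, -1.09, and VEGFA, -0.68), at adjusted p = 0.539. Cholesterol synthesis genes fell in 7 and rose in 2 of 18 cases (ACAT2, -1.20, IDI1, -0.78, SREBF2, -0.66, HMGCS1, 0.55) with adjusted p = 0.05. Extracellular matrix and mesenchymal genes had 5 of 34 higher (FBN1, 1.02) and 9 lower (COL5A2, -1.32, COL6A3, -0.64), at adjusted p = 0.689. ER chaperones had 3 of 19 higher (EDEM1, 0.73) and 5 lower (DNAJC3, -0.66), at adjusted p = 0.872, and heat shock genes 5 of 13 higher (CRYAB, 0.85), at adjusted p = 0.18. Adjusted over the list alone, these 5 lists had 9, 2, 5, 4 and 7 members higher and 10, 7, 9, 5 and 0 lower, in the order given. Kidney tubule epithelial markers had 7 of 19 higher (EPCAM, 1.04) and 2 lower (adjusted p = 0.577), also adjusted over the list alone. Markers of immune cells (1 of 12 higher, CD74, 0.35), endothelial cells (0 of 10) and fibroblasts and pericytes (1 of 12 higher, RGS5, 0.44) had adjusted p of 0.741, 0.907 and 0.848. Adjusted over the list alone, 1, 0 and 0 members were higher, and neither of the 2 other RGS5 probe sets was called.

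The direction of YAP silencing was the same under erastin for nearly all of the genes above. CCL20 was 11.2-fold higher, SCN3A 5.84-fold, CCN3 4.81-fold, CPEB3 4.72-fold and AGT 4.58-fold. Falls were again led by LYRM1 (6.39-fold lower), OSTM1 (5.98-fold lower), SUV39H2 (from 5.84 to 3.26, again near the bottom of the scale), the peroxisome gene PEX2 (5.77-fold lower) and PLOD2 (5.3-fold lower). In limma 4173 genes passed, 2397 higher and 1776 lower, and 316 changed at least 2-fold (144 higher, 172 lower). No array was shared between this comparison and the one in DMSO.

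Across all 11963 genes, which are not independent replicates, the log2 fold changes of both comparisons correlated at r = 0.907 (Spearman's rho = 0.753). A total of 1741 genes were higher in both, where independent lists would share 433.8, and 1393 were lower in both, where 276.9 would be shared. Only 6 genes passed in both with opposite directions.

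**Figure D2:**
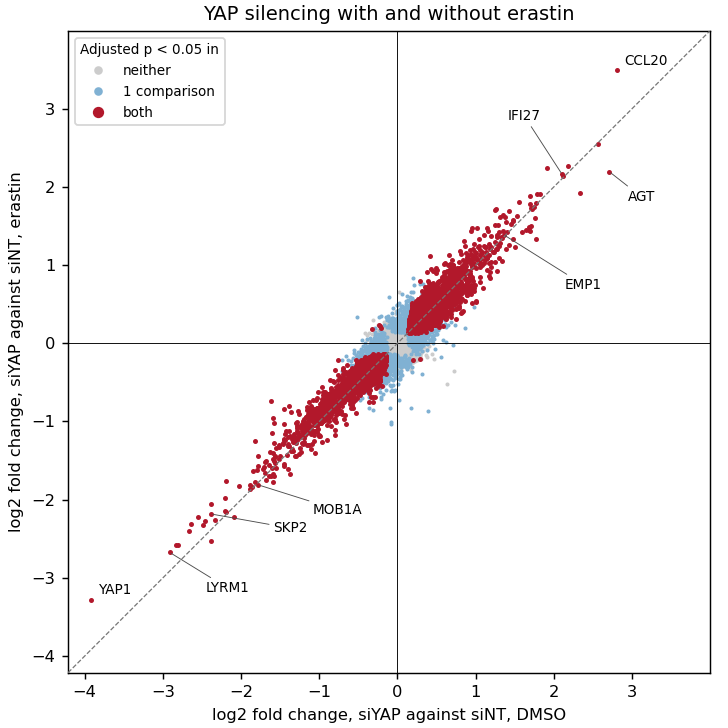
Log2 fold change of siYAP against siNT for 11963 genes in DMSO (horizontal axis) and under erastin (vertical axis); each point is a gene, coloured by whether adjusted p was under 0.05 in neither, 1 or both comparisons, and the dashed line marks equal change. Points follow the line (r = 0.907), with YAP1, LYRM1 and SKP2 among the falls and CCL20 as the largest rise.

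Under erastin 36 of 37 S phase genes fell (CCNE2, -1.84, CDC45, -1.82, MCM10, -1.69, PRIM1, -1.62), as did 32 of 34 genes of G2 and mitosis (HMMR, -1.41, KIF23, -1.40, CDC25C, -1.33, CCNB2, -1.32), the same counts as adjusted over the list alone. Their set tests gave adjusted p = 1.18e-37 and 1.56e-39, and adjusted p = 0.111 and 0.118 with an estimated correlation. On the ATF4 list 23 of 36 fell and 2 rose (24 and 3 adjusted over the list alone), with DDIT4 down by 1.17 and CTH, the cystathionine-cleaving enzyme that makes cysteine, by 1.05. Its adjusted p was 9.26e-10, 0.0475 with an estimated correlation, and 0.17 with the replicate block and an estimated correlation together. Interferon response genes rose in 18 and fell in 1 of 29 cases (20 and 1 adjusted over the list alone, adjusted p = 1.53e-04, and adjusted p = 0.513 with an estimated correlation), among them IFI27 (2.16), IFI6 (1.33), ISG20 (1.27) and ISG15 (1.20). NF-kB and cytokine genes rose in 16 and fell in 1 of 24 cases (17 and 1 adjusted over the list alone, adjusted p = 3.4e-06, and adjusted p = 0.111 with an estimated correlation), among them CCL2 (1.48), CXCL2 (0.97) and IL6 (0.93).

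Cholesterol synthesis genes passed as a set here, with 8 of 18 lower and 3 higher, also adjusted over the list alone (adjusted p = 0.0135, and adjusted p = 0.127 with an estimated correlation). ACAT2 fell by 1.21, SREBF2 by 1.03 and IDI1 by 0.81. YAP/TAZ targets (4 of 19 higher, 6 lower, adjusted p = 0.664) and Hippo pathway genes (6 of 18 higher, 2 lower, adjusted p = 0.88) did not pass, and adjusted over the list alone gave the same counts. ANKRD1 (0.68) and CCN2 (0.45) rose and AMOTL2 (-0.54) and AXL (-0.38) fell, as did MOB1A (-1.81), while TEAD1 rose by 0.63. NRF2 targets (adjusted p = 0.18), p53 targets (adjusted p = 0.645) and immediate early genes (adjusted p = 0.112) did not pass as sets in camera. Directional fry called each of them upward (adjusted p = 5.07e-04, 0.00374 and 1.74e-04). SPRY2 (1.29), TP53I3 (1.42) and AKR1C3 (1.05) rose and PMAIP1 (-1.65) and GCLM (-0.89) fell. NRF2 targets had 7 members higher and 2 lower, p53 targets 6 and 5, and immediate early genes 5 and 1; adjusted over the list alone these were 7 and 2, 7 and 5, and 5 and 1.

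Of the ferroptosis genes, SKP2 was 4.55-fold lower, EMP1 2.62-fold higher and ACSL4 lower by 0.54 (adjusted p = 0.00111). GPX4 rose by 0.28 (adjusted p = 0.00981), ANGPTL4 by 0.31 (adjusted p = 0.00129), ALOX5 by 0.87 and TFRC by 0.14 (adjusted p = 0.0493). CHAC1 fell by 0.74. SLC7A11 (0.17, adjusted p = 0.0714) and NOX4 (0.14, adjusted p = 0.457) did not pass. Of the promoting genes 5 rose and 5 fell and of the protective genes 3 rose and 2 fell, also adjusted over the list alone, without a set shift (adjusted p = 0.68 and 0.848, with medians and means of opposite sign). Camera called no shift for hypoxia-inducible factor targets (7 higher, 9 lower, adjusted p = 0.204), matrix genes (6 higher, 8 lower, adjusted p = 0.539), ER chaperones (6 higher, 9 lower, adjusted p = 0.734) or heat shock genes (4 higher, 1 lower, adjusted p = 0.15), for which the list alone gave 7 and 11, 7 and 9, 6 and 9, and 8 and 1. Directional fry called hypoxia-inducible factor targets downward (adjusted p = 0.00262) and heat shock genes upward (adjusted p = 1.09e-05), but not matrix genes or ER chaperones. Markers of tubule (5 higher, 2 lower, adjusted p = 0.833), immune (1 higher, adjusted p = 0.872), endothelial (1 lower, adjusted p = 0.715) and fibroblast (1 lower, adjusted p = 0.695) cells did not shift either. Adjusted over the list alone, 0 fibroblast markers were lower, and the other counts were the same. The log2 difference between 3' and 5' ACTB control probe sets, a sign of RNA integrity, was 3.54 ± 0.179 (SD, n = 3) in siYAP with erastin, against 2.26 ± 0.69 in siNT with erastin, 2.59 ± 0.955 in siYAP with DMSO and 2.68 ± 0.282 in siNT with DMSO. For GAPDH it was 0.169 ± 0.0385, 0.146 ± 0.076, 0.216 ± 0.0118 and 0.182 ± 0.0681 in the same order. With the ACTB difference as a covariate, 3065 genes passed for silencing under erastin, of which 2839 were among the 4173.

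**Figure D3:**
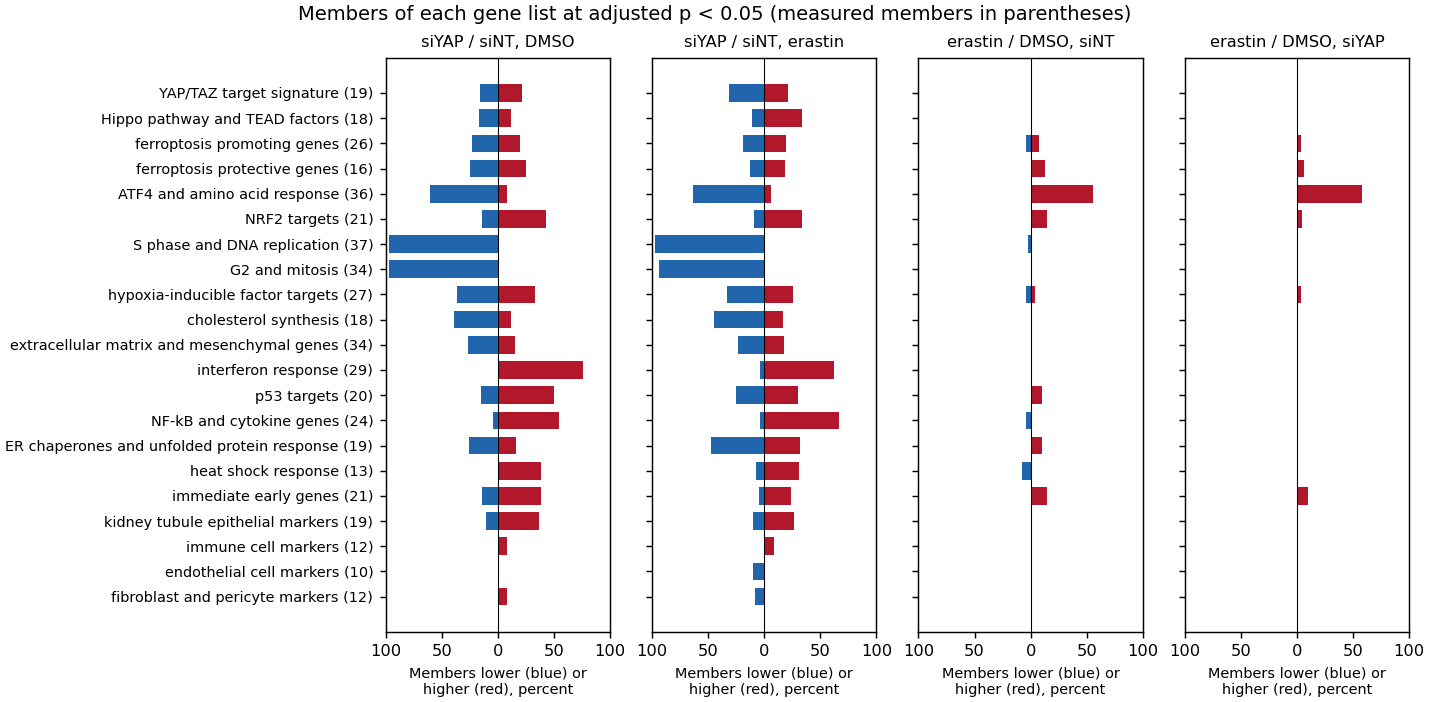
Share of the measured members of each fixed gene list (rows, number of members in parentheses) that were higher (red) or lower (blue) at adjusted p under 0.05, in percent, for YAP silencing in DMSO and under erastin and for erastin in siNT and siYAP cells. S phase and mitosis genes were lower in both silencing comparisons (36 of 37 and 33 of 34 in DMSO), and the ATF4 list was lower with silencing and higher with erastin.

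In control cells, erastin raised genes of the ATF4 and amino acid response. CHAC1 was 3.1-fold higher, DDIT4, an inhibitor of mTORC1, 2.86-fold and CTH 2.27-fold. SLC7A11 rose by 0.87 (SE 0.067), from 8.85 ± 0.05 to 9.72 ± 0.12 (SD, n = 3), ASNS by 0.81 and STC2 and ATF3 by 0.77 each. INHBE, an activin subunit gene that is not on the fixed list, was 2.93-fold higher. On the ATF4 list 20 of 36 rose and none fell, and 30 rose adjusted over the list alone. As a set it had adjusted p = 2.81e-141, and adjusted p = 1.63e-04 with an estimated correlation.

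In limma 90 genes passed, 58 higher and 32 lower, and the 4 that changed at least 2-fold were higher. Falls were small: BCL2A1 (-0.58, adjusted p = 0.047), CCL2 (-0.55), the phosphatase gene DUSP7 (-0.52), RGS2 (-0.49), HBEGF (-0.46), PLAUR (-0.46), RGS4 (-0.46) and TMEM158 (-0.44). Of these only DUSP7, RGS2 and HBEGF were called under all 15 of the block, trended, weighted and leave-1-out fits. YAP1 itself differed by 0.01 (adjusted p = 0.998), SKP2 by -0.17 (adjusted p = 0.777), EMP1 by -0.09 (adjusted p = 0.858), ACSL4 by -0.03 (adjusted p = 0.965), TFRC by 0.06 (adjusted p = 0.749), GPX4 by 0.01 (adjusted p = 0.988), WWTR1 by -0.02 (adjusted p = 0.964) and NOX4 by 0.07 (adjusted p = 0.927). ANGPTL4 fell by 0.30 (adjusted p = 0.0427).

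Of p53 targets 2 of 20 rose, GDF15 (0.69) and CDKN1A (0.24), and 4 rose adjusted over the list alone (set adjusted p = 9.48e-06, and 0.0475 with an estimated correlation). With the replicate block and an estimated correlation together the p53 set was not called (adjusted p = 0.17). Further sets passed upward, each with few members called. They were NRF2 targets (3 of 21, HMOX1, 0.69, AKR1C1, 0.38, and SLC7A11, adjusted p = 2.11e-08), immediate early genes (3 of 21, ATF3, KLF4, 0.76, and EGR1, 0.47, adjusted p = 1.62e-05), ferroptosis protective genes (2 of 16, SLC7A11 and SLC3A2, 0.40, adjusted p = 0.014) and hypoxia-inducible factor targets (1 of 27 higher, STC2, and ANGPTL4 lower, adjusted p = 0.0219). With an estimated correlation their adjusted p was 0.111, 0.194, 0.467 and 0.542, and adjusted over the list alone 5, 3, 2 and 2 members were higher. SLC7A11 and SLC3A2 are also on the ATF4 list. Sets that passed downward were S phase (CCNE1, -0.32, the 1 of 37 called, adjusted p = 3.23e-09), G2 and mitosis (0 of 34, adjusted p = 0.00116), NF-kB and cytokine genes (CCL2, the 1 of 24 called, adjusted p = 1.6e-04) and heat shock genes (DNAJB1, -0.26, the 1 of 13 called, adjusted p = 0.00669). With an estimated correlation their adjusted p was 0.29, 0.631, 0.118 and 0.111, and adjusted over the list alone 3, 0, 7 and 2 members were lower. The ER genes HERPUD1 (0.52) and XBP1 (0.51) rose, without a shift of their list (adjusted p = 0.664, its median below 0 and its mean and test above), as did HMOX1 and CARS1 (0.25) on the list of ferroptosis promoting genes (adjusted p = 0.379).

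The remaining 9 lists did not pass and had no member called. The count of 90 depended on single arrays: it was 35, 38 and 44 without siNT with DMSO replicates 1, 2 and 3, 34 and 57 without siNT with erastin replicates 1 and 3, and 53 and 52 without siYAP with erastin replicates 1 and 3. It was 15 when only the 6 arrays of both groups were fitted and 323 with array weights, where 45.2% of the calls were higher against 64.4%.

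After YAP silencing, erastin again raised genes of the ATF4 list. CHAC1 was 3.12-fold higher, SLC7A11 2.39-fold, DDIT4 2.21-fold, SLC1A4 2.17-fold, ASNS 2.17-fold and CTH 2.04-fold, and the folate enzyme gene MTHFD2 1.82-fold. SLC7A11 went from 8.63 ± 0.09 to 9.89 ± 0.01 (SD, n = 3). INHBE, outside the list, went from 4.43 ± 0.09 to 6.56 ± 0.07, and the size of its rise is uncertain because it started near the level of the markers of other cell types. On the ATF4 list 21 of 36 rose and none fell (28 adjusted over the list alone), with adjusted p = 3.45e-154, and adjusted p = 1.63e-04 with an estimated correlation.

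In limma 40 genes passed, 39 higher and 1 lower, the latter being HBEGF (-0.35, adjusted p = 0.0287), an EGF receptor ligand gene. CARS1 (0.52), STC2 (0.68), KLF4 (0.73) and ATF3 (0.31) rose. YAP1 (0.64, adjusted p = 0.494), SKP2 (0.03, adjusted p = 0.971), EMP1 (-0.06, adjusted p = 0.891), ACSL4 (-0.01, adjusted p = 0.987), ANGPTL4 (-0.04, adjusted p = 0.876), TFRC (0.01, adjusted p = 0.975), GPX4 (0.11, adjusted p = 0.623), WWTR1 (-0.12, adjusted p = 0.468) and NOX4 (0.05, adjusted p = 0.924) did not pass. Without siYAP with erastin replicate 2 the values of YAP1 and SKP2 were 0.17 and -0.21, and without siYAP with DMSO replicate 1 that of YAP1 was 0.42. Ferroptosis protective genes shifted upward, with SLC7A11 the 1 of 16 called (adjusted p = 1.53e-04, and adjusted p = 0.202 with an estimated correlation). The median log2 change of this list was 0.05, and SLC7A11 is also on the ATF4 list. S phase genes (0 of 37 called, adjusted p = 2.82e-04) and heat shock genes (0 of 13 called, adjusted p = 0.0169) shifted downward, with adjusted p = 0.565 and adjusted p = 0.118 with an estimated correlation. Adjusted over the list alone, 1, 0 and 1 members of these lists passed. The other 17 lists did not pass as sets in camera, while directional fry called the ferroptosis promoting genes upward (adjusted p = 0.0189). Median, mean and test differed in sign for the Hippo, NRF2, mitosis, hypoxia-inducible factor, ER, immediate early and immune lists.

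The mean ACTB 3' to 5' difference was 3.54 in siYAP with erastin and 2.59 in siYAP with DMSO, where replicate 2 had 1.49 and the others 3.142 and 3.145. That of GAPDH went the other way (0.169 and 0.216). With the ACTB difference as a covariate 22 genes passed. Without siYAP with DMSO replicates 1 or 2 the count was 24 or 20, without siYAP with erastin replicates 2 or 3 it was 22 or 20, with the 6 arrays alone it was 26, and with a trended, robust variance model it was 74, where 68.9% of calls were higher against 97.5%.

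**Figure D4:**
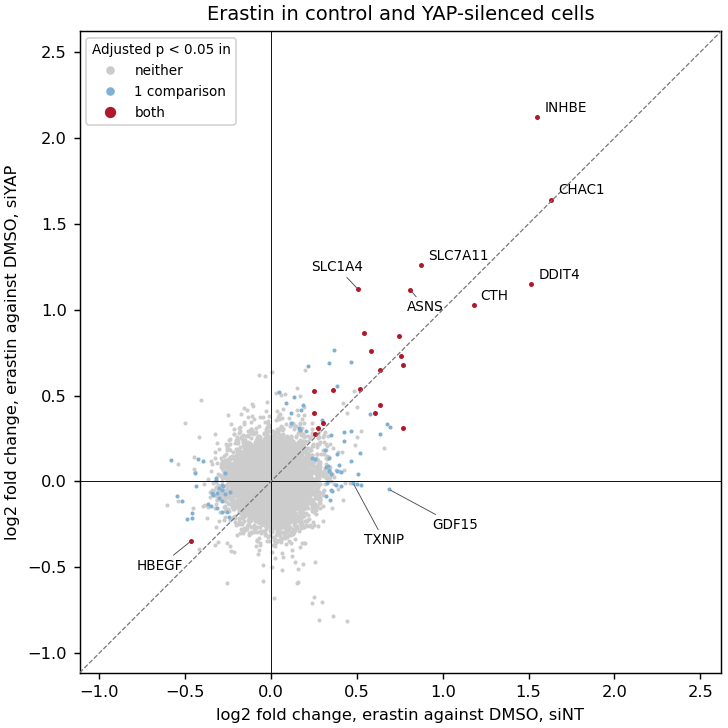
Log2 fold change of erastin against DMSO for 11963 genes in siNT cells (horizontal axis) and siYAP cells (vertical axis); each point is a gene, coloured by whether adjusted p was under 0.05 in neither, 1 or both comparisons, and the dashed line marks equal change. INHBE, CHAC1, DDIT4 and SLC7A11 were higher in both, and most genes lie around 0.

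The erastin response did not pass the planned limma test of a difference between control and YAP-silenced cells for any of 11963 genes, while a trended, robust variance model called 8 genes and array weights 1. In the planned test 0 genes passed (smallest adjusted p = 0.153), with 1179 at an unadjusted p under 0.05 where 598 would be expected by chance. Genes that vary together between arrays can move such a count far from 598, so the excess does not show differing responses. For CHAC1 the difference was 0.01 (95% interval -0.19 to 0.21). For SLC7A11 the rise was larger by 0.39 after silencing (95% interval 0.18 to 0.60, adjusted p = 0.354). Differences were 0.26 for ANGPTL4 (adjusted p = 0.422), 0.20 for SKP2 (adjusted p = 0.786), 0.10 for GPX4 (adjusted p = 0.775) and 0.02 for ACSL4 (adjusted p = 0.977). For EMP1, TFRC, WWTR1, NOX4 and YAP1 they were 0.03, -0.06, -0.10, -0.02 and 0.63, with adjusted p of 0.97, 0.843, 0.684, 0.981 and 0.657. Without siYAP with erastin replicate 2 the values of YAP1 and SKP2 were 0.16 and -0.04, and without siYAP with DMSO replicate 1 that of YAP1 was 0.41.

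Of the genes that passed in either erastin comparison (106), 83% had the same sign in both, 23 were higher in both, where independent lists would share 0.189, and 1 (HBEGF) was lower in both. Over all 11963 genes the correlation of both erastin responses was r = 0.129 (Spearman's rho = 0.0151). Simulated data had the spread of these arrays, independent noise and 200 of 11963 genes changed. On them the interaction test called 6% of genes with a difference of 0.25 on the log2 scale, 62% of those with 0.5 and 100% of those with 1. With fewer changed genes these shares would be lower, so they are not the power for the real data. As sets, 6 of the 21 lists differed in camera (p53 targets, NRF2 targets, YAP/TAZ targets and immediate early genes downward, NF-kB genes and G2 and mitosis upward), with adjusted p from 4.68e-05 to 0.0343 and, with an estimated correlation, adjusted p from 0.0609 to 0.796. Directional fry called 1 of the 21 lists and mixed fry 10.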

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

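The tests of explanations in this part were chosen after the results were seen, except the list tests of the interaction, which were planned. In that interaction test no single gene passed, but 6 of 21 fixed lists did in camera with the preset correlation. With an estimated correlation none of the 6 did, with adjusted p of 0.0609 for p53 targets, 0.264 for NRF2 targets, 0.268 for YAP/TAZ targets, 0.29 for immediate early genes, 0.331 for NF-kB genes and 0.796 for G2 and mitosis. They are given here because camera with the preset correlation called a difference in erastin response between control and YAP-silenced cells. For p53 targets the adjusted p was 4.68e-05 over 20 members, with a median log2 change of 0.08 with erastin in control cells and -0.04 after silencing. GDF15 had the largest difference among them (-0.73, adjusted p = 0.272), then ZMAT3 (-0.51, adjusted p = 0.503), both named after their values were seen. Downward differences were also found for YAP/TAZ targets (adjusted p = 0.014, median difference -0.07, 19 members), NRF2 targets (adjusted p = 0.0135, median difference -0.09, 21 members) and immediate early genes (adjusted p = 0.014, median difference -0.05, 21 members). Upward differences were found for G2 and mitosis (adjusted p = 0.0343, median difference 0.08, 34 members) and NF-kB and cytokine genes (adjusted p = 0.0193, median difference 0.13, 24 members).

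Members of a list that vary together between arrays could give such shifts without an effect of silencing. With the correlation estimated from these arrays none passed, the lowest adjusted p being 0.0609. Of all 21 lists, directional fry called 1 for the interaction and mixed fry 10. The ACTB 3' to 5' difference was highest in siYAP with erastin, that of GAPDH was not (0.169, against 0.216 in siYAP with DMSO). With the ACTB difference as a covariate and the preset correlation, 2 of the 6 lists still passed. They were p53 targets (adjusted p = 0.0079) and NF-kB genes (adjusted p = 0.0431). The ACTB difference moves with the groups, so the covariate cannot tell for any of the 6 lists whether it is a cause. Over 21 other settings, all with the preset correlation, p53 targets passed in each (adjusted p from 6.75e-06 to 0.0079). The other lists failed in 3 to 8 of them. In 1 setting siNT with erastin replicate 3 and siYAP with erastin replicate 2 were left out together. There p53 targets (adjusted p = 0.00692) and NF-kB genes (adjusted p = 0.0195) passed in camera. YAP/TAZ targets (0.136), NRF2 targets (0.25), immediate early genes (0.251) and G2 and mitosis (0.471) did not. Silencing in DMSO had itself raised 10 of 20 p53 targets and lowered 3. GDF15 stood at 11.20 in siNT and 11.76 in siYAP with DMSO, and at 11.89 and 11.71 with erastin. A weaker p53-linked response to erastin after YAP silencing therefore cannot be told apart from a changed starting level, and was not tested further.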

How the results depend on the processing

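The ACTB covariate, the removal of both arrays in doubt and the block with an estimated correlation were chosen after seeing the data; other settings were planned. For named genes 5361 results kept their direction and side of the threshold, 281 lost the call, 9 gained it and 67 turned their sign; for lists these were 2299, 110, 45 and 66. Mixed fry, which has no direction, kept the side for 63 lists, lost 3 and gained 39. YAP silencing in DMSO (4030 genes) gave 6079 probe sets when each was tested on its own, 324 genes with a 2-fold minimum and 254 with the zero transformation; under erastin (4173) these were 6415, 316 and 219. Erastin in control cells (90) gave 15 with the 6 arrays alone, 138 without the dimmest probe sets, 161 with a trended, robust model, 323 with array weights, 41 without both arrays in doubt, 4 at 2-fold and 4 with the zero transformation. Erastin after silencing (40) gave 26 with the 6 arrays alone, 74 with the trended, robust model, 73 with array weights (82.2% higher), 22 with the ACTB covariate, 7 at 2-fold and 6 with the zero transformation. The interaction (0) gave 8 with the trended, robust model and 1 with array weights. List shifts (34 of 105) became 5 with an estimated correlation, 70 with mixed fry and 2 with the block and an estimated correlation: the rises of the ATF4 list with erastin were called (adjusted p = 0.00369 each), while its falls with YAP silencing in DMSO and under erastin and the rise of p53 targets were not (adjusted p = 0.17 each). Stricter thresholds and more tests account for themselves. For other settings, those with fewer arrays included, the cause was not tested.

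Leaving out each array gave 3424 to 4311, 3443 to 4256, 34 to 76, 20 to 45 and 0 to 0 genes for the 5 comparisons, 30 to 37 list shifts, and a correlation of 0.889 to 0.915 between the silencing effects. Of the 90 erastin calls in control cells 28 were called under all 15 of the block, trended, weighted and leave-1-out fits, and 19 of 40 after silencing. Replicate numbers did not pair the samples: 1 of 18 same-numbered pairs had deviations correlated over 0.1 (median -0.02) and 1 of 12 arrays correlated best with its own number. With the replicate block the counts were 3850, 3972, 38, 28 and 0, and 35 list shifts. Genes near the bottom of the scale, such as NOX4, show little of a change.

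The sign turned for 19 named gene results, 67 times over the settings, and for 31 list results, 66 times. None of these passed in the fit of the report or where its sign turned, and the cause was not tested. The log2 changes of these genes with the other sign follow. With the mean of probe sets they were WWTR1 0.13 and SLC7A11 -0.068 for silencing under erastin, SKP2 -0.14, EMP1 0.023 and TFRC -0.024 for erastin after silencing and SKP2 -0.042 for the interaction. With the ACTB covariate they were NOX4 -0.10 for silencing under erastin, YAP1 -0.062 for erastin in control cells and SKP2 -0.027, EMP1 0.017, ACSL4 0.054, TFRC -8e-04 and NOX4 -0.13 for erastin after silencing. With array weights they were YAP1 -0.060 and WWTR1 0.0069 for erastin in control cells. With both arrays in doubt left out they were YAP1 -0.046 for erastin in control cells, SKP2 -0.21 for erastin after silencing and SKP2 -0.065 and NOX4 0.074 for the interaction. With arrays centred on their medians they were TFRC -0.0093 for erastin after silencing and CHAC1 -0.0095 for the interaction. With quantile normalization they were ACSL4 -0.025, CHAC1 -0.008 and NOX4 0.0011 for the interaction. Leaving out each array gave them these ranges. Erastin in control cells gave YAP1 -0.046 to 0.046, WWTR1 -0.056 to 0.022, ACSL4 -0.14 to 0.055, GPX4 -0.046 to 0.10 and NOX4 -0.044 to 0.14. Erastin after silencing gave SKP2 -0.21 to 0.17, ANGPTL4 -0.071 to 0.0011, ACSL4 -0.066 to 0.065, TFRC -0.017 to 0.029 and NOX4 -0.090 to 0.14. The interaction gave SKP2 -0.040 to 0.34, EMP1 -0.042 to 0.15, ACSL4 -0.063 to 0.13, CHAC1 -0.031 to 0.061 and NOX4 -0.16 to 0.095.

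The adjusted p of the lists with the other direction follow. With quantile normalization they were endothelial 0.984 for silencing in DMSO and ER 0.848 and immune 0.935 for erastin after silencing. With dim probe sets left out they were fibroblast 0.998 for silencing in DMSO and Hippo 0.998 for erastin after silencing. With the mean of probe sets they were ferroptosis protective 0.947 for silencing under erastin and ferroptosis promoting 0.542, ATF4 0.973 and heat shock 0.886 for the interaction. With array weights they were Hippo 0.997 for silencing in DMSO, Hippo 0.946 and interferon 0.979 for erastin in control cells, ER 0.997 for erastin after silencing and Hippo 0.997 for the interaction. With the ACTB covariate they were Hippo 0.894 and immune 0.841 for silencing under erastin, Hippo 0.739, p53 0.806 and ER 0.841 for erastin after silencing and Hippo 0.896 and ferroptosis promoting 0.85 for the interaction. With both arrays in doubt left out they were ER 0.992 for silencing in DMSO, Hippo 0.934 and ferroptosis protective 0.977 for silencing under erastin and Hippo 0.935 and immune 0.767 for erastin after silencing. With an estimated correlation they were Hippo 0.977 for silencing in DMSO, ferroptosis protective 0.977 for silencing under erastin, ER 0.977 for erastin in control cells and hypoxia-inducible factor 0.977 for erastin after silencing. With directional fry they were Hippo 0.907 for silencing in DMSO and ER 0.785 for erastin after silencing. With the replicate block and an estimated correlation they were YAP/TAZ 0.957 and Hippo 0.955 for silencing in DMSO, ferroptosis protective 0.955 for silencing under erastin, ER 0.955 for erastin in control cells and hypoxia-inducible factor 0.955 for erastin after silencing. Leaving out each array gave these ranges of adjusted p. Silencing in DMSO gave endothelial 0.831 to 0.974 and Hippo 0.796 to 0.969. Erastin in control cells gave matrix 0.339 to 0.934, immune 0.21 to 0.871, endothelial 0.148 to 0.934 and fibroblast 0.111 to 0.942. The interaction gave heat shock 0.658 to 0.997, immune 0.298 to 0.898, ferroptosis promoting 0.729 to 0.984, interferon 3.63e-05 to 0.737 and S phase 0.0117 to 0.877. Silencing under erastin gave ferroptosis protective 0.761 to 0.984, immune 0.761 to 0.92 and Hippo 0.84 to 0.992. Erastin after silencing gave ER 0.827 to 0.987, Hippo 0.624 to 0.92, mitosis 0.00581 to 0.873, interferon 9.44e-05 to 0.545, NF-kB 0.357 to 0.829, immune 0.741 to 0.964 and matrix 0.505 to 0.962. The lowest of these kept their direction: interferon without siYAP with DMSO replicate 1 in both comparisons, mitosis without siYAP with erastin replicate 2 and S phase without siYAP with DMSO replicate 3.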

Other observations

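The tests of explanations in this part, the gene families, their scalings and the counts of largest changes were chosen after the results were seen; the other splits of the arrays were planned. Genes were grouped by the letters before the number in their symbols, which gave 149 families of at least 10 genes, tested with camera over 4 comparisons (596 tests), of which 7 families passed in at least 1 comparison. Besides nucleoporins (NUP) and CXCL, these were CDC, CEP, KIF, MCM and RAD, all downward with silencing (adjusted p = 0.993 with an estimated correlation). CDC, KIF and MCM share members with the cell cycle lists. Nucleoporins fell with YAP silencing: 18 of 21 were lower and none higher in DMSO (median log2 change -0.42, adjusted p = 9.43e-09), and 17 under erastin (adjusted p = 2.07e-07), with adjusted p = 0.473 with an estimated correlation in both. NUP54 fell by 1.60, NUP50 by 1.18 and NUP58 by 1.16 in DMSO. Of 12 CXCL chemokines 7 rose in each comparison, of which 6 rose in both (adjusted p = 0.0114 and 0.0133, and adjusted p = 0.993 with an estimated correlation). CXCL1, CXCL2, CXCL3, CXCL5, CXCL6 and CXCL8 are also on the NF-kB and cytokine list. With arrays centred on their medians or quantile normalized, the medians of the nucleoporin and CXCL families kept their signs.

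Some histone genes outside any list were higher after silencing while those of DNA replication were lower. H2AC6 rose by 1.56, H2BC12 by 1.43 and H2BC5 by 1.35 in DMSO, and by 1.80, 1.69 and 1.64 under erastin. In a set of 42 histone genes 8 rose and 3 fell in DMSO, and 9 rose and 5 fell under erastin. The 8 are 19% of them, against 18.1% of all genes, and the set test gave p = 0.0422, and p = 0.584 with an estimated correlation. Their median was 0.018 in DMSO, and under erastin it changed sign between scalings (0.00349, and -0.00566 with arrays centred on their medians). Their sequences are close, so a probe set may read several of them.

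Falls outnumbered rises among the largest effects of YAP silencing in DMSO, where 65.7% of 324 genes changed at least 2-fold were lower, as were 16 of the 20 and 69 of the 100 largest changes. Under erastin 54.4% of 316 such genes were lower, and the zero transformation gave 108 higher and 111 lower. An siRNA acting on further transcripts would give such an excess, and so would the loss of an activator; no siRNA sequence was used here, and the 65.7% cannot separate them. Loss of YAP activity read from the fixed target list gave a median of -0.0081 over members that went both ways, which decides nothing, so this stays open too. Without both cell cycle lists 61.5% of the remaining 288 genes were lower, but those lists hold only 36 of the 213 falls, so fewer transcripts of dividing cells may still account for part.

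In siYAP with erastin, replicate 2 kept more YAP1 (6.21) than replicates 1 and 3 (4.68 and 4.90). Noise of the YAP1 probe set alone is argued against: of 212 other genes at least 2-fold lower in DMSO, a comparison without this array, 90.1% were highest in replicate 2 of its group. A share of unsilenced cells or control RNA may be present, which the falling genes put on the linear scale at a median of 12.9% (middle 50% from 9.27% to 17.5%), near the 13.4% from YAP1 and 14.7% from SKP2. Rising genes gave a median of 5.89% (-0.329% to 12.8%), which is too wide to tell, and weaker silencing in every cell stays open.

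For YAP silencing in DMSO the 10 splits of 6 arrays into 3 and 3 are too few for a share under 0.05. In 1 of the 10, the real one, as many as 4030 genes were called, and the highest other gave 0. Under erastin it was again 1 of 10 (4173, highest other 0). For erastin in control cells it was 1 of 10 (90, highest other 10, when siNT with erastin replicate 3 changed places with siNT with DMSO replicate 3), and after silencing 1 of 10 (40, highest other 0). For the interaction the real count was 0, which all of the 100 splits drawn within each siRNA reach by construction, so they say nothing about chance. The highest other split called 103 genes; it turned the treatment labels of the siYAP arrays around, which makes the interaction the sum of both erastin responses. Of the 99 other splits 3 called any gene.

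The 8 genes called by the trended, robust interaction test were GDF15 (-0.73), TXNIP (-0.49), ATF3 (-0.46), ALDH1A1 (-0.43), JAG1 (-0.41), HLA-G (-0.39), TMEM158 (0.49) and SLC1A4 (0.61), with adjusted p from 0.0148 to 0.0435; in the limma fit of the report the adjusted p ranged from 0.153 to 0.354. SLC1A4 was also called with array weights (0.66, adjusted p = 0.0197).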
